A study of Mus musculus with 64 samples.

How the data were processed

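Gene expression was measured by BRB-seq, a bulk RNA barcoding method that counts the 3′ ends of transcripts, in livers of male C57BL/6J mice fed ad libitum. The mice had received an AAV8 vector carrying a hairpin against Acsf3 (sh-Acsf3) or a control hairpin (sh-Ctl) 4 weeks earlier. Livers were taken at 8 zeitgeber times (ZT, hours after lights on) spaced 3 h apart, with 4 replicates per treatment and time, which gives 16 groups and 64 libraries. Per the labels, the authors aligned the reads with STAR to the GRCm38/mm10 assembly and counted unique molecular identifiers (UMIs) per gene. The deposited values are raw UMI counts without normalization. The versions used, the annotation release and the settings for merging UMIs were not stated.

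The table held 55487 genes, of which 23436 had at least 1 UMI. Totals ran from 0.839 to 9.35 M UMIs per library with a median of 2.79 M, so a gene at 1 CPM (counts scaled to a common library total) is held by a few UMIs per library, and single libraries give weak genes little precision. All 64 columns were matched to the labels by treatment, time and replicate number. Replicates of a group differed in every one of 96 pairs by more than counting error (lowest chi-square per degree of freedom 2.84), so none was a copy of another. Gene positions came from GENCODE release M21, in which 10092 of the 10097 tested identifiers and 215 of 215 identifiers of named genes were found.

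Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the groups (minimum count 10, minimum total 15), which left 10097, and library sizes were scaled by TMM. A quasi-likelihood model with 16 group means was fitted after robust estimation of the spread (common biological coefficient of variation 0.189, 48 residual degrees of freedom). The contrasts were sh-Acsf3 minus sh-Ctl averaged over the 8 times, the same difference at each time, and a test with 7 degrees of freedom that the 8 differences are equal. Rhythms were tested in a model with a mean and a 24 h cosine and sine per treatment (58 residual degrees of freedom), for each treatment and for the difference between treatments. The amplitude ratio was the median log2 ratio of sh-Acsf3 to sh-Ctl amplitude over genes rhythmic by the mean of both treatments, from least squares fits of log2 CPM with a prior count of 2. P values were adjusted by Benjamini-Hochberg over genes within each test, with a threshold of 0.05.

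The 37 gene lists (metabolic and stress pathways, the core clock, and markers of liver and foreign cell types) were tested on the averaged contrast with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were alternatives. Of 680 listed entries 613 were tested, and counts and medians of list members cover the tested ones. The lists, the contrasts, the tests and the rule for named genes were set before the data were examined. Named genes were Acsf3; the 10 largest rises and 10 largest falls of the averaged effect among genes past the threshold, with mean CPM of at least 5 and the same sign in at least 7 of 8 times; up to 4 members of each list with the smallest p; up to 3 genes up and 3 down per time with the smallest p; the core clock list and the 10 largest sh-Ctl amplitudes; and the 10 and 5 genes with the smallest p for differential rhythmicity and interaction, passing or not. Members of near-identical families such as the Mup, Saa and haemoglobin genes can share reads.

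Alternatives were RLE size factors, library size only, no gene filter, a mean CPM of at least 5 (at least 20 for the amplitude ratio), DESeq2 1.42.0, limma-voom, a block for replicate number, an additive model, fits on single times or treatments, cosines of 24 h and 12 h, and leaving out each replicate number, the shallowest library and, for the averaged and single-time effects and the averaged gene lists, each library. Leaving out libraries with high Saa1 or with pancreas RNA was added after the data had been seen. Treatment labels were exchanged within times 100 times, all 35 splits were run at each time, and time labels were permuted 100 times. On simulated counts the averaged test found 62%, 86%, 96% and 100% of 50 genes changed 1.25-, 1.5-, 2- and 4-fold, with 5 false calls among 177. For genes changed at ZT12 alone, the interaction test found 24% of those changed 2-fold and 82% of those changed 4-fold. For rhythms present in sh-Ctl alone, the differential test found 36% at a peak to trough fold of 2 and 92% at a fold of 4. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.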

Results

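The data are UMI counts per gene from 64 liver libraries, with 32 from sh-Ctl and 32 from sh-Acsf3 mice and 4 per treatment at each of 8 zeitgeber times. Totals were 1.48 to 6.06 M UMIs in sh-Ctl (median 3.13) and 0.839 to 9.35 M UMIs in sh-Acsf3 (median 2.03). Between 11824 and 16276 genes were detected per library. Transcripts of the mitochondrial genome took 18.7% ± 2.20 of the counts in sh-Ctl and 19.4% ± 2.46 in sh-Acsf3 (SD, n = 32 each). In 4 sh-Ctl libraries (ZT9 replicate 1, and replicate 2 at ZT12, ZT15 and ZT18) Saa1, an acute-phase gene, lay at 2092 to 4204 CPM, against at most 250.9 CPM in the others. In 8 libraries, 2 from sh-Ctl and 6 from sh-Acsf3, the summed CPM of pancreas enzyme genes was 159 to 7560, against at most 27.2 in the others. The order of the library numbers follows the treatment, and the labels give no preparation batch.

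The first comparison asks how far the hairpin lowered its target over the day. Acsf3 (ENSMUSG00000015016) encodes a mitochondrial enzyme that makes malonyl-CoA from malonate, and fell to 21.3% of its control level, from 11.3 ± 2.61 to 2.56 ± 1.72 CPM (SD, n = 32 each). The averaged difference was -2.23 ± 0.13 (log2, SE), with an edgeR adjusted p of 1.82e-21. These values rest on 1114 UMIs in sh-Ctl and 233 in sh-Acsf3. The gene lies on the plus strand of chromosome 8 from 122775486 to 122817880 (GRCm38), with 3 annotated protein-coding transcripts of 10 exons each, and Gm20388 overlaps it on the same strand. Across the day the difference was -3.11 ± 0.39 at ZT0, -2.28 ± 0.37 at ZT3, -3.21 ± 0.38 at ZT6 and -2.57 ± 0.37 at ZT9 (log2, SE, n = 4 per group). It was -1.501 ± 0.33 at ZT12, -1.91 ± 0.35 at ZT15 and -1.77 ± 0.36 at ZT18, and each of these 7 passed the test. At ZT21 the difference of -1.53 ± 0.42 did not pass (edgeR adjusted p = 0.0814), with 9.23 ± 2.86 CPM in sh-Ctl and 3.46 ± 3.19 in sh-Acsf3 (SD, n = 4 each), and passed with -2.47 (adjusted p = 0.0131) without sh-Acsf3 ZT21 replicate 1. Without sh-Ctl ZT15 replicate 4 or sh-Acsf3 ZT15 replicate 1 the edgeR adjusted p at ZT15 became 0.109 or 0.0598. At ZT18 it became 0.0576, 0.0609 or 0.15 without sh-Ctl replicate 2, 3 or 4 and 0.306 without sh-Acsf3 replicate 1. Acsf3 showed no detectable daily rhythm in sh-Ctl (amplitude 0.22 ± 0.16 log2, SE, edgeR adjusted p = 0.405).

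**Figure D1:**
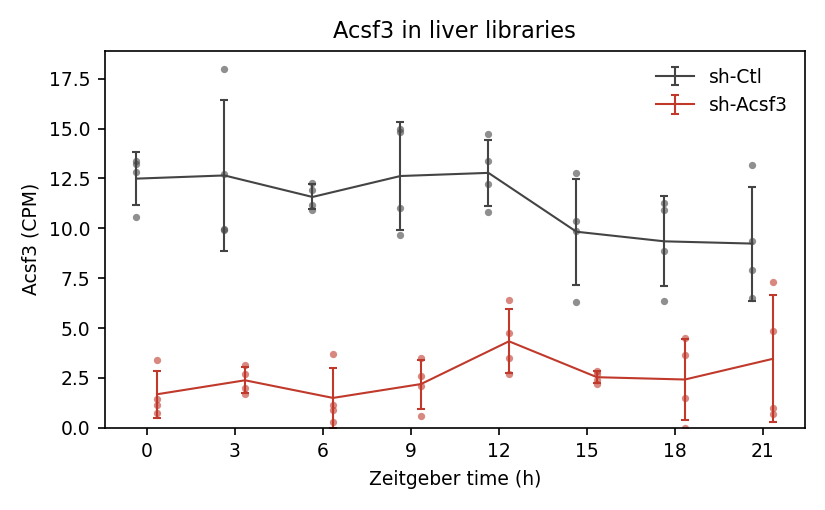
Acsf3 in CPM (vertical axis) by zeitgeber time in hours (horizontal axis). Points are single libraries and lines with bars are the mean and SD of 4 libraries per treatment and time; sh-Acsf3 libraries reach at most 7.31 CPM and the lowest sh-Ctl library holds 6.32 CPM.

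The second comparison asks which liver transcripts differed between treatments over the whole day. Among genes with a mean of at least 5 CPM and the same sign at 7 or more of the 8 times, the 10 with the largest rises are given first. Ccl5, a chemokine made by T and NK cells, rose by 3.38 ± 0.14 (log2, SE) from 2.58 ± 1.502 to 26.3 ± 7.79 CPM (SD within times, n = 32 each). The MHC class II genes Cd74, H2-Eb1, H2-Aa and H2-Ab1, which serve antigen presentation, rose by 1.65, 1.63, 1.61 and 1.503, and the immunoglobulin light chain gene Igkc rose by 1.55 ± 0.22. The fibrillar collagen genes Col1a1, Col3a1 and Col1a2 rose by 2.03 ± 0.17, 1.55 ± 0.12 and 1.51 ± 0.11. Ccnd1, which encodes cyclin D1, rose by 1.55 ± 0.11, from 38.1 ± 11.5 to 114 ± 34.0 CPM. All 10 of these were higher in sh-Acsf3 at all 8 times.

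Besides Acsf3, the 10 largest falls under the same limits held 7 members of the Mup family, whose products are major urinary proteins made by the liver and whose reads can be shared between members. Mup9, Mup17, Mup18 and Mup11 changed by -3.21 ± 0.39, -2.93 ± 0.37, -2.55 ± 0.32 and -2.52 ± 0.27, and Mup16, Mup12 and Mup14 by -2.19 ± 0.26, -1.79 ± 0.18 and -1.17 ± 0.18 (log2, SE). Cyp2c40, a cytochrome P450 gene, fell by 2.18 ± 0.26, from 11.5 ± 7.69 to 2.71 ± 2.35 CPM (SD within times, n = 32 each). Moxd1, which encodes a monooxygenase-like protein, changed by -4.16 ± 0.70, from 10.3 ± 15.0 to 0.435 ± 0.683 CPM. The Moxd1 call ended without sh-Ctl ZT0 replicate 4, with a difference of -3.48 and an edgeR adjusted p of 1.

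In total 1461 of 10097 genes passed the edgeR test, 834 higher and 627 lower, and 97 of the rises and 26 of the falls were at least 2-fold. The difference had the same sign at all 8 times for 789 of them and at 7 or more times for 1276. With library size only in place of TMM, 1125 rose and 247 fell, as the median difference of all genes moved from -0.0085 to 0.0456. Without the 4 libraries high in Saa1 the count was 1408, and without the 8 with pancreas RNA it was 1184, of which 1242 and 1111 were among the 1461. Without replicate 3 of every group the count was 784, of which 760 were among them.

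**Figure D2:**
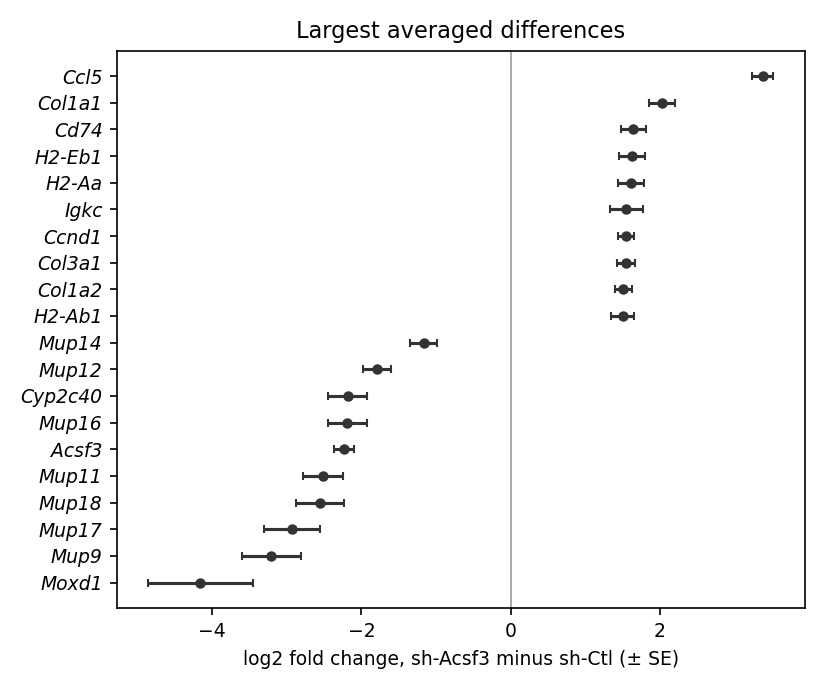
Averaged log2 fold change (sh-Acsf3 minus sh-Ctl, horizontal axis) of the genes with the largest rises and falls at a mean of at least 5 CPM and with the same sign at 7 or more times (vertical axis), with bars of 1 SE, from 64 libraries. Of the genes drawn, Ccl5 lies highest at 3.38 and Moxd1 lowest at -4.16.

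Markers of several other cell types of the liver were higher in sh-Acsf3. Of the 15 tested stellate cell and fibroblast markers 12 rose and none fell (15 rose when adjusted over the list alone), with a median difference of 0.77. Among them were Dcn, which encodes the proteoglycan decorin, at 0.74 ± 0.05 from 150 ± 20.7 to 250 ± 40.0 CPM (SD within times, n = 32 each), and Col14a1 at 0.87 ± 0.08. Of the 7 tested lymphocyte markers 6 rose (6 adjusted over the list alone), with a median of 2.24. They included Nkg7 at 2.68 ± 0.20 and Gzma at 2.74 ± 0.28, both of cytotoxic cells, and the T cell receptor gene Trbc2 at 2.24 ± 0.20. The other members of the lymphocyte list were not tested, and the count filter can keep a gene by its level in sh-Acsf3 alone. Both lists passed camera (adjusted p = 9.45e-36 and 2.37e-21), also with an estimated correlation (adjusted p = 5.31e-07 each). Without the 8 libraries with pancreas RNA, 12 stellate and 5 lymphocyte markers rose, with medians of 0.78 and 2.19. Of 14 sinusoidal endothelial markers only Eng, an endothelial receptor of the TGF-beta family, rose (0.27 ± 0.06, 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.184).

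Of 12 Kupffer cell and macrophage markers 6 rose (9 adjusted over the list alone), among them the scavenger receptor gene Marco at 1.72 ± 0.25, Cd68 at 0.83 ± 0.13 and the complement gene C1qc at 0.62 ± 0.10 (log2, SE). The list passed camera (adjusted p = 4.2e-07) but lost its call at adjusted p = 0.219 with an estimated correlation. Of 7 monocyte and neutrophil markers 5 rose (5 adjusted over the list alone), such as Cybb, a subunit of the phagocyte oxidase, at 0.56 ± 0.11, and Plac8 at 0.55 ± 0.12. Camera gave that list adjusted p = 8.45e-05, and adjusted p = 0.175 with an estimated correlation. Of 4 cholangiocyte markers Spp1, the osteopontin gene, rose by 0.68 ± 0.12 and Epcam, a gene of epithelial adhesion, by 0.61 ± 0.17 (3 rose when adjusted over the list alone). That list gave a camera adjusted p of 0.00753, and adjusted p = 0.128 with an estimated correlation.

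Of 16 cell cycle genes 10 rose and none fell (14 adjusted over the list alone), with a median of 0.66. Cdk1, the kinase of mitotic entry, rose by 1.05 ± 0.21, Mcm6, a part of the replicative helicase, by 0.80 ± 0.17, and Top2a, a topoisomerase of dividing cells, by 1.29 ± 0.28. The list passed camera (adjusted p = 2.2e-07), with adjusted p = 0.178 with an estimated correlation. Of 13 pericentral hepatocyte genes 7 rose (7 adjusted over the list alone), among them the ammonium transporter gene Rhbg at 0.88 ± 0.16, Gulo, an enzyme of vitamin C synthesis, at 0.36 ± 0.07, and Lect2 at 0.31 ± 0.06. Camera gave an adjusted p of 0.00753 for it, with adjusted p = 0.427 with an estimated correlation. Without the libraries with pancreas RNA it became 0.0631, with 6 genes up. Of 12 periportal hepatocyte genes 3 fell (3 adjusted over the list alone), led by Hal, an enzyme of histidine breakdown, at -0.27 ± 0.07 and Cyp2f2 at -0.19 ± 0.05, and the list did not pass (camera adjusted p = 0.184).

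No member of the exocrine pancreas and adipose list passed the test among 12 tested (0 adjusted over the list alone), although the list passed camera (adjusted p = 0.00901), with adjusted p = 0.648 with an estimated correlation. Ctrb1, a chymotrypsinogen gene, differed by 3.01 ± 1.26 and Pnlip, the pancreatic lipase gene, by 2.81 ± 1.41, and neither passed. Without sh-Acsf3 ZT21 replicate 2 these differences were 1.358 and 1.76. With library size only the camera adjusted p was 0.0767. It was 0.0666 without sh-Acsf3 ZT12 replicate 2, 0.35 without sh-Acsf3 ZT21 replicate 2, which is also the shallowest library, and without all 8 libraries with pancreas RNA the direction turned (adjusted p = 0.747). Of 5 red blood cell genes none passed (0 adjusted over the list alone, camera adjusted p = 0.471), with Alas2, the first enzyme of haem synthesis in red cells, at 0.15 ± 0.07.

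**Figure D3:**
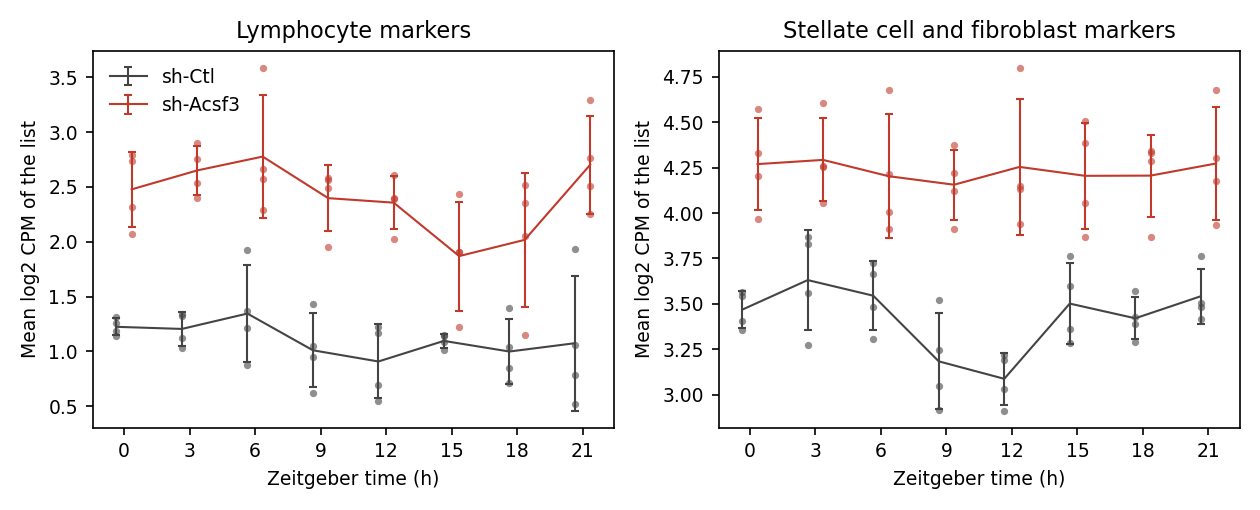
Mean log2 CPM of the lymphocyte markers (left) and of the stellate cell and fibroblast markers (right) by zeitgeber time in hours. Points are single libraries and lines with bars are the mean and SD of 4 libraries per treatment and time; 31 of 32 and 32 of 32 sh-Acsf3 libraries lie above all sh-Ctl libraries of their time.

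All 14 tested Mup genes, which lie on chromosome 4 between 59956804 and 62150863, fell, with a median of -1.46 and a range of -3.21 to -0.39 (log2). All 14 also fell with RLE size factors and with library size only. Fewer passed in other settings, with 13 by limma-voom and without replicate 1, 12 without the libraries with pancreas RNA, 11 without replicate 4 and 10 without replicate 3, though all 14 differences stayed below 0 in each. Their summed level was 47245 ± 15409 CPM in sh-Ctl and 24809 ± 5567 in sh-Acsf3 (SD, n = 32 each), and 25 of 32 sh-Acsf3 libraries lay below all sh-Ctl libraries of their time. Of the 19 male-biased and growth hormone-dependent genes, 10 fell and 1 rose (11 and 2 adjusted over the list alone). Mup3 and Mup7, which can share reads with other Mup genes, changed by -0.53 ± 0.08 and -1.09 ± 0.20, Nudt7, a peroxisomal hydrolase gene, by -0.32 ± 0.07, and Cyp4a12b, a fatty acid hydroxylase gene, by 0.45 ± 0.10. The list passed camera downwards (adjusted p = 0.000306), with adjusted p = 0.381 with an estimated correlation.

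Of 70 nuclear-encoded genes of the respiratory chain and ATP synthase 21 fell and none rose (34 and 0 adjusted over the list alone), with a median of -0.09. Examples were the complex I genes Ndufv1 at -0.21 ± 0.04 (161 ± 18.3 to 140 ± 14.2 CPM, SD within times, n = 32 each) and Ndufb5 at -0.17 ± 0.04. The list passed camera (adjusted p = 2.2e-07), with adjusted p = 0.427 with an estimated correlation. With library size only 5 fell and 1 rose, and without the libraries with pancreas RNA 12 fell. Of 15 genes of bile acid synthesis and transport 6 fell and 1 rose (6 and 1 adjusted over the list alone). The bile acid uptake gene Slc10a1 changed by -0.28 ± 0.06 and the phospholipid exporter gene Abcb4 by 0.27 ± 0.06, and with library size only 1 fell and 1 rose. That list passed camera (adjusted p = 0.00665), with adjusted p = 0.175 with an estimated correlation.

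Of 25 acute-phase genes 10 fell and none rose (14 and 0 adjusted over the list alone), with a median of -0.29. Lbp, which encodes a lipopolysaccharide-binding protein, changed by -0.47 ± 0.09, the plasma protein gene Itih4 by -0.50 ± 0.13, and Orm2, a gene of an abundant acute-phase plasma protein, by -2.52 ± 0.56. The list passed camera (adjusted p = 0.00791), with adjusted p = 0.651 with an estimated correlation, and with library size only 5 members fell. All 4 libraries high in Saa1 are sh-Ctl. Without them 5 members were higher and 2 lower in sh-Acsf3, the median was 0.13, the list turned upwards (camera adjusted p = 0.0532), and Orm2 stood at 0.13. Leaving out sh-Ctl ZT9 replicate 1, ZT12 replicate 2 or ZT15 replicate 2 alone gave camera adjusted p of 0.0649, 0.0732 and 0.0818.

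**Figure D4:**
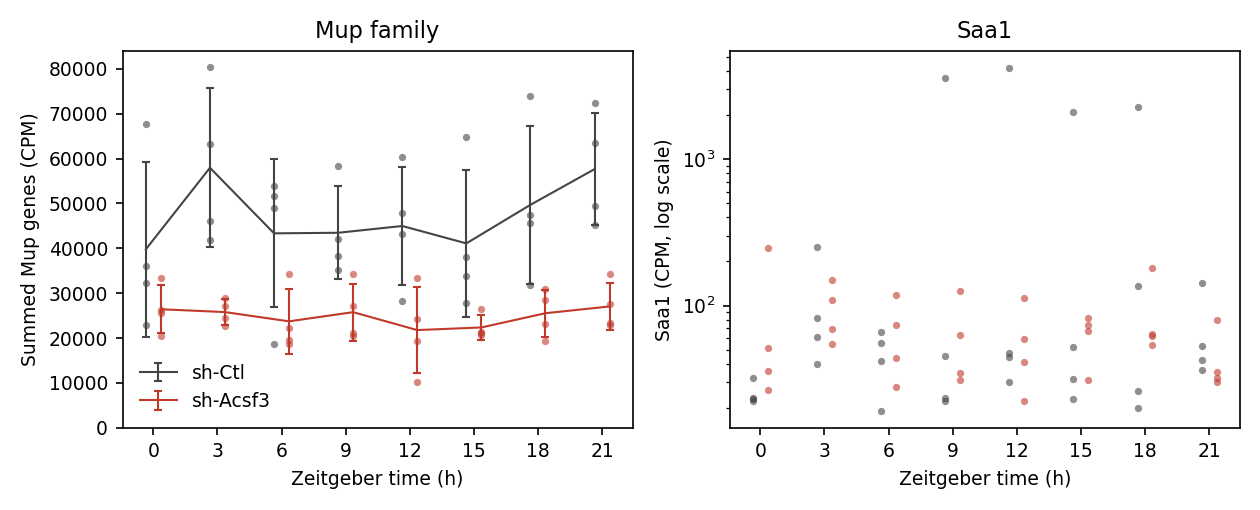
Summed CPM of the Mup genes (left, with mean and SD of 4 libraries per treatment and time) and Saa1 in CPM on a log axis (right), by zeitgeber time in hours. Points are single libraries, and 4 sh-Ctl libraries lie between 2092 and 4204 CPM of Saa1.

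The other lists tested on the averaged effect did not pass camera. Without the libraries high in Saa1, the list of mitochondrial fatty acid oxidation passed downwards (camera adjusted p = 0.0366, median -0.06). So did the list of the TCA cycle and pyruvate dehydrogenase (camera adjusted p = 0.0246, median -0.08). The list of cholesterol synthesis and uptake passed upwards there (camera adjusted p = 0.0246, median 0.15). Of 16 genes of malonyl-CoA handling, mitochondrial fatty acid synthesis and lipoylation, the pathway next to Acsf3, only Dlat, a lipoylated part of pyruvate dehydrogenase, fell (-0.25 ± 0.07, 1 adjusted over the list alone, list adjusted p = 0.184), and its call ended with library size only. The lysine deacylase gene Sirt3 differed by 0.16 ± 0.09 and did not pass. None of 19 genes of mitochondrial fatty acid oxidation passed (0 adjusted over the list alone, list adjusted p = 0.173), with Hadha at 0.12 ± 0.05 and Etfa at -0.09 ± 0.04. Of 22 genes of the TCA cycle and pyruvate dehydrogenase 1 rose and 5 fell (1 and 6 adjusted over the list alone, list adjusted p = 0.075), with Idh2, an isocitrate dehydrogenase gene, at 0.27 ± 0.05 and Sdha, a succinate dehydrogenase gene, at -0.15 ± 0.04. With library size only 3 of them rose and 0 fell. Of 7 mitochondrially encoded genes none passed (1 rose and 1 fell when adjusted over the list alone, list adjusted p = 0.376). Of 22 genes of branched-chain amino acid and propionate breakdown 3 fell (3 adjusted over the list alone, list adjusted p = 0.072), including Mccc2, a carboxylase gene of leucine breakdown, at -0.17 ± 0.04, whose call ended with library size only. Of 16 genes of lysine, tryptophan and tyrosine breakdown 1 rose and 3 fell (1 and 5 adjusted over the list alone, list adjusted p = 0.219), with Kmo at -0.22 ± 0.05 and Acmsd at 0.51 ± 0.14, both in the kynurenine pathway.

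In lipid and sugar metabolism, 4 of 23 genes of fatty acid and triglyceride synthesis rose and 2 fell (4 and 3 adjusted over the list alone, list adjusted p = 0.803). Scd2, a desaturase gene, changed by 0.73 ± 0.14, Fads2, also a desaturase gene, by 0.31 ± 0.07, and Dgat2, of the last step of triglyceride synthesis, by -0.29 ± 0.05. Of 24 genes of cholesterol synthesis and uptake 2 rose (1 adjusted over the list alone, list adjusted p = 0.072). Of 23 PPARalpha targets Acot2, a mitochondrial thioesterase gene, rose by 0.56 ± 0.16 (1 adjusted over the list alone, list adjusted p = 0.376). Of 6 ketogenesis genes Bdh1, a ketone body dehydrogenase gene, rose by 0.24 ± 0.06 (1 adjusted over the list alone, list adjusted p = 0.772). Of 15 genes of glycolysis and glucose uptake 3 fell (3 adjusted over the list alone, list adjusted p = 0.0918), among them the fructokinase gene Khk at -0.32 ± 0.08. Of 15 genes of gluconeogenesis and fasting 1 rose and 1 fell (1 and 4 adjusted over the list alone, list adjusted p = 0.279), the fall being Insr, the insulin receptor gene, at -0.17 ± 0.05, whose call ended with library size only. Of 14 glycogen genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, list adjusted p = 0.549), with glycogenin, Gyg, at 0.46 ± 0.13. Of 12 genes of the urea cycle and ammonia handling Oat, of ornithine metabolism, rose by 0.41 ± 0.10 and Glud1, glutamate dehydrogenase, changed by -0.16 ± 0.04 (1 and 1 adjusted over the list alone, list adjusted p = 0.376), the latter not with library size only.

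Of 17 genes of xenobiotic metabolism 2 rose and 3 fell (3 and 5 adjusted over the list alone, list adjusted p = 0.376), with the cytochrome P450 genes Cyp3a11 at 0.43 ± 0.06 and Cyp2c37 at -1.16 ± 0.12. Of 14 NRF2 targets, genes of the antioxidant response, 3 rose (3 adjusted over the list alone, list adjusted p = 0.072), led by the glutathione transferase gene Gstm3 at 1.02 ± 0.21. Of 9 p53 targets Cdkn1a, the p21 gene, rose by 0.92 ± 0.21 and Btg2, also a gene that restrains growth, by 0.76 ± 0.16 (4 adjusted over the list alone, list adjusted p = 0.08), and the Cdkn1a call ended with limma-voom. Of 17 genes of the integrated and mitochondrial stress responses 2 rose and 1 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.882), with the stress transcription factor gene Atf3 at 1.01 ± 0.27. Of 21 genes of the ER unfolded protein response 2 fell (2 adjusted over the list alone, list adjusted p = 0.075), including Pdia6, a disulfide isomerase gene, at -0.31 ± 0.06. None of 13 heat shock and temperature-responsive genes passed (0 adjusted over the list alone, list adjusted p = 0.336), with Hspa1b at -0.33 ± 0.21. Of 24 interferon response genes 2 rose and 3 fell (3 and 4 adjusted over the list alone, list adjusted p = 0.937). Gbp2, a GTPase gene induced by interferon gamma, changed by 1.01 ± 0.18 and Ifit1, an antiviral gene, by -0.73 ± 0.16, and the list's median and mean were -0.06 and -0.02 while camera pointed up. Of 18 core clock and clock output genes Hlf, a PAR bZIP transcription factor gene, fell by 0.25 ± 0.06 (1 adjusted over the list alone, list adjusted p = 0.32).

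The third comparison asks which genes differed at single times of day. Ccl5 rose at all 8 times, by 2.80 ± 0.34 at ZT6 up to 4.16 ± 0.45 at ZT18 (log2, SE, n = 4 per group). Ccnd1 and, besides the genes of the fixed rule, Mmp12, a macrophage elastase gene named after its values were seen, rose at 7 times each. At ZT0 Cdkn2c, a CDK inhibitor gene, rose by 1.63 ± 0.27 and Marcks by 0.98 ± 0.19, while Cyp2c37 changed by -1.55 ± 0.33 and Sgpp1, a sphingosine phosphate phosphatase gene, by -0.64 ± 0.14. At ZT3 Vcam1, an adhesion molecule for leukocytes, rose by 1.81 ± 0.34. At ZT6 Cdkn2c rose by 1.26 ± 0.23 and Pnkd by 0.96 ± 0.18, while Cyp2u1 changed by -0.75 ± 0.17 and Sgpp1 by -0.62 ± 0.14. At ZT9 Vcam1 rose by 2.32 ± 0.35 and Dcn by 1.06 ± 0.15, while Dct changed by -1.54 ± 0.35 and Psmc1, a proteasome subunit gene, by -0.51 ± 0.12. At ZT12 the matrix genes Sparc and Bgn rose by 1.37 ± 0.19 and 1.34 ± 0.19, while Dct, Cyp2c37 and Kalrn changed by -1.87 ± 0.36, -1.77 ± 0.34 and -0.99 ± 0.19. At ZT15 the only calls were Ccl5 at 3.07 ± 0.41, Ccnd1 at 1.45 ± 0.29 and Acsf3. At ZT18 the collagen chaperone gene Serpinh1 rose by 1.44 ± 0.26 and Dcn by 0.76 ± 0.15, while Car1 and Cib2 changed by -1.04 ± 0.25 and -1.03 ± 0.24. At ZT21 Vim, which encodes vimentin, rose by 1.32 ± 0.25 and Bgn by 1.05 ± 0.19, while Yod1, Ttc17 and Maco1 changed by -1.12 ± 0.24, -1.03 ± 0.21 and -0.65 ± 0.15.

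By edgeR, 52 genes passed at ZT0 (47 higher, 5 lower), 7 at ZT3 (6 and 1), 22 at ZT6 (19 and 3) and 36 at ZT9 (31 and 5). There were 141 at ZT12 (117 and 24), 3 at ZT15 (2 and 1), 17 at ZT18 (14 and 3) and 32 at ZT21 (28 and 4). Of the 185 genes called at any time 172 were also called in the averaged effect. Leaving out 1 library of the time gave 9 to 53 genes at ZT0, 3 to 10 at ZT3, 7 to 41 at ZT6, 15 to 32 at ZT9, 47 to 256 at ZT12, 1 to 5 at ZT15, 1 to 13 at ZT18 and 9 to 54 at ZT21. Without the libraries with pancreas RNA there were 23 at ZT0, 12 at ZT6, 14 at ZT9, 238 at ZT12, 1 at ZT15, 10 at ZT18 and 14 at ZT21.

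The fourth comparison asks whether the knockdown effect differed between times. No gene passed the edgeR interaction test, and 306 had an unadjusted p under 0.05. Evenly spread p values would give 505, and exchanged treatment labels gave a median of 447. DESeq2 and limma-voom also called 0 genes, with 229 and 407 at an unadjusted p under 0.05. The smallest p belonged to Pml, a nuclear body gene (edgeR adjusted p = 0.9999), which differed by 1.06 ± 0.26 at ZT12 and -0.59 ± 0.23 at ZT0 (log2, SE, n = 4 per group). Next came Pnlip, the ribosomal RNA gene n-R5-8s1, the trypsin-like gene 2210010C04Rik and the deubiquitinase gene Yod1, none of which passed (edgeR adjusted p = 0.9999 each). Pnlip and 2210010C04Rik are pancreas genes, and the 8 libraries with pancreas RNA lie at ZT0, ZT3, ZT9, ZT12 and ZT21 in sh-Acsf3 and at ZT6 and ZT15 in sh-Ctl. Without a gene filter 273 genes were called, led by these pancreas genes, since the fit then took the spread of all 23436 genes from the common trend with level alone.

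The fifth comparison describes daily rhythms in each treatment. Clock genes cycled strongly in both. Dbp, a clock output transcription factor gene, had an amplitude of 2.64 ± 0.15 in sh-Ctl and 2.78 ± 0.15 in sh-Acsf3 (log2, SE, n = 32 each), with peaks at ZT 10.8 and 10.9. Arntl, which encodes BMAL1, peaked at ZT 22.5 and 22.8 with amplitudes of 1.88 ± 0.15 and 1.71 ± 0.15, and Nr1d1, which encodes REV-ERB alpha, at ZT 7.75 and 8.01 with 2.34 ± 0.19 and 2.07 ± 0.19. Per2, a repressor of the clock, peaked at ZT 15.6 and 15.5 with amplitudes of 1.24 ± 0.16 and 1.49 ± 0.16, and Cry1, also a repressor, at ZT 20.2 and 20.0 with peak to trough folds of 5.65 and 5.11. Npas2, Clock, Per1, Per3, Nr1d2, Tef, Hlf, Nfil3, Ciart and Bhlhe40 were also rhythmic in both. Cry2 passed in sh-Acsf3 (edgeR adjusted p = 0.00228) and not in sh-Ctl (0.359), and Rora in sh-Ctl (0.0321) and not in sh-Acsf3 (0.415), but neither difference passed its own edgeR test (adjusted p = 0.9995 for both). The Rora call ended with library size only. Among the 10 largest sh-Ctl amplitudes were also Rgs16 (2.15 ± 0.27 and 1.39 ± 0.27), Ciart (2.10 ± 0.17 and 2.20 ± 0.17), Usp2 (2.10 ± 0.17 and 1.84 ± 0.17), Elovl3 (1.83 ± 0.16 and 1.97 ± 0.16), Tubb2a (1.67 ± 0.14 and 1.28 ± 0.14), Chka (1.58 ± 0.12 and 1.41 ± 0.12) and Noct (1.57 ± 0.19 and 1.43 ± 0.19), in sh-Ctl and sh-Acsf3 in turn.

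By edgeR, 1954 genes were rhythmic in sh-Ctl and 1981 in sh-Acsf3, of which 1182 were in both, where independence would give 383. The sh-Ctl count was 1167 without replicate 4 of every group, and the sh-Acsf3 count was 1173 and 1163 without replicate 2 and 3. Among the 1182 genes, 996 (84.3%) peaked within 2 h of each other, with a median shift of -0.289 h in sh-Acsf3. A test of any difference between the 8 times, with 7 degrees of freedom, gave 1271 and 1319 genes.

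**Figure D5:**
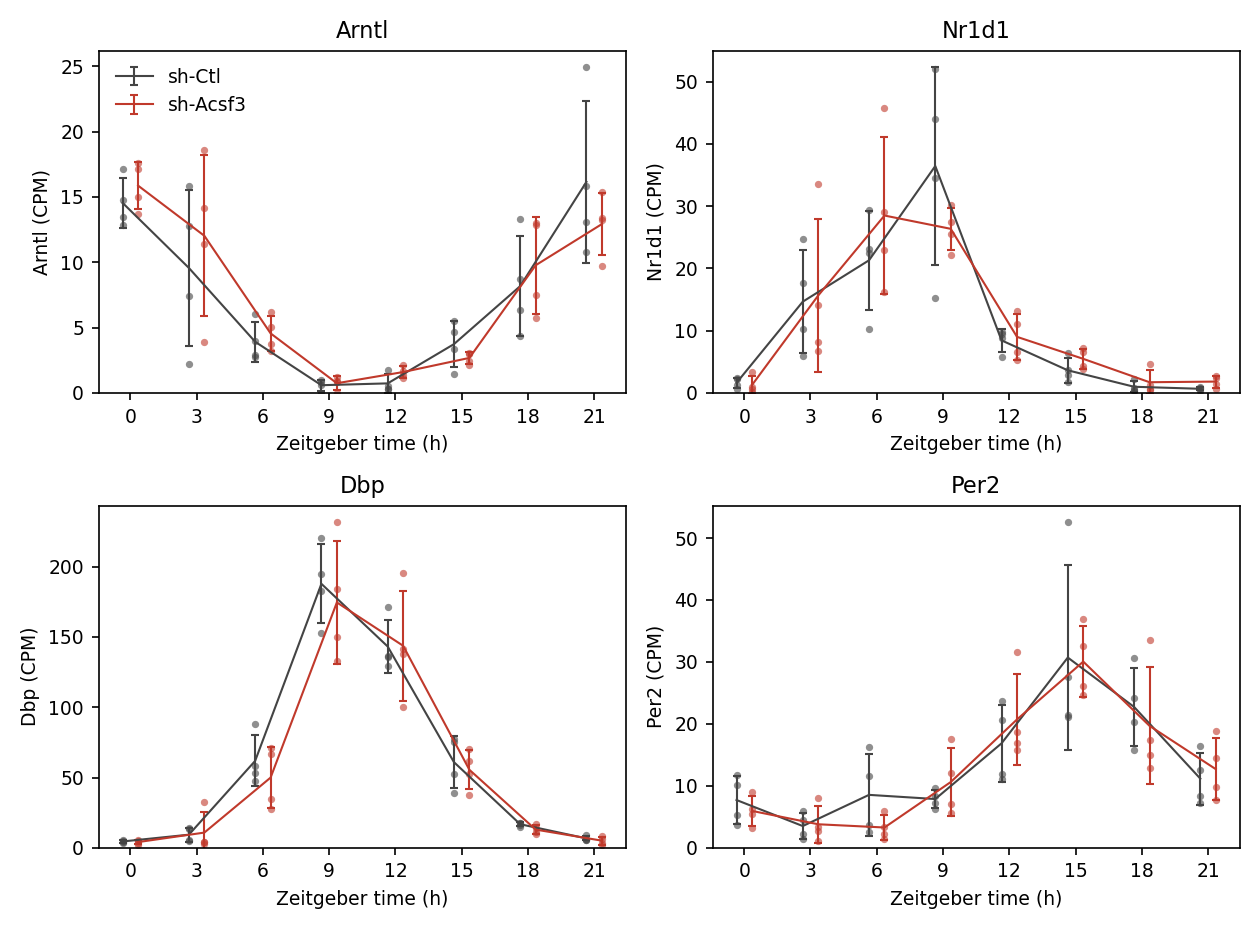
CPM of 4 clock genes by zeitgeber time in hours; points are single libraries and lines with bars are the mean and SD of 4 libraries per treatment and time. The peaks of Arntl lie at ZT 22.5 in sh-Ctl and 22.8 in sh-Acsf3.

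The sixth comparison asks whether rhythms differed between treatments. No gene passed the edgeR test of differential rhythmicity (lowest adjusted p 0.591). An unadjusted p under 0.05 was found for 431. Evenly spread p values would give 505, and exchanged treatment labels gave a median of 400. DESeq2 and limma-voom also called 0, with 461 and 504 at an unadjusted p under 0.05. The smallest p belonged to Gm49201, with fitted peaks at ZT 19.1 in sh-Ctl and 11.3 in sh-Acsf3, and to Slc17a8, a glutamate transporter gene with amplitudes of 0.98 ± 0.14 and 0.52 ± 0.14 (log2, SE, n = 32 each), and neither passed (edgeR adjusted p = 0.591 each). The acute-phase genes Saa3, Mt2, Saa2 and Mt1, of which the Saa genes can share reads, were also among the 10 smallest p and did not pass. Saa3 had amplitudes of 0.86 ± 0.31 in sh-Ctl and 0.06 ± 0.31 in sh-Acsf3, and Mt1, a metallothionein gene, of 1.14 ± 0.27 and 0.51 ± 0.27. The 4 sh-Ctl libraries high in Saa1 lie at ZT9, ZT12, ZT15 and ZT18. Ddx28, Adar, Sfxn5 and Hemk1 completed the 10 and did not pass either. Over 3569 genes rhythmic by the mean of both treatments, the median log2 ratio of sh-Acsf3 to sh-Ctl amplitude was 0.05, with quartiles of -0.34 and 0.45. It was -0.03 without the libraries high in Saa1 and 0.12 without those with pancreas RNA.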

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

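The tests of the hepatocyte share, of shared Mup reads, of a weaker growth hormone pattern and of swapped labels, and the runs without libraries high in Saa1 or with pancreas RNA, were chosen only after the results were seen. Totals, Acsf3 and Saa1 in every group, and the genes named at single times, gave 122 groups of 4 libraries. In 14 of them a library's gap to the nearest of the others, as a share of the range, exceeded Dixon's critical value. Chance gives about 1 in 20, or 6.1 here. Saa1 was not a gene of the fixed rule, so its flags cannot be set against that number.

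The total was 6.064 M UMIs in sh-Ctl ZT6 replicate 1 (others 3.257 to 3.641) and 9.351 M UMIs in sh-Acsf3 ZT0 replicate 3 (others 1.638 to 2.579). Saa1 stood apart in 9 groups, so most of the 14 came from it. In sh-Ctl it was 31.76 CPM in ZT0 replicate 1 (others 22.15 to 23.36), 3604 in ZT9 replicate 1 (22.26 to 45.51), 4204 in ZT12 replicate 2 (30.25 to 47.7), 2092 in ZT15 replicate 2 (23.16 to 51.96), 2259 in ZT18 replicate 2 (20.02 to 135.6) and 143.5 in ZT21 replicate 3 (36.02 to 52.93). In sh-Acsf3 it was 246.9 CPM in ZT0 replicate 3 (others 26.65 to 51.3), 180.8 in ZT18 replicate 2 (53.91 to 64.22) and 80.02 in ZT21 replicate 3 (29.84 to 35.1). Vcam1 was at 9.122 CPM in sh-Acsf3 ZT9 replicate 4 (others 12.39 to 12.9). Ccnd1 was at 37.52 CPM in sh-Ctl ZT15 replicate 2 (others 55.09 to 58.14). Yod1 was at 9.741 CPM in sh-Acsf3 ZT21 replicate 3 (others 16.38 to 16.95).

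The mean log2 CPM of stellate and lymphocyte markers was higher in sh-Acsf3 by 0.81 ± 0.06 and 1.30 ± 0.10 (SE, n = 32 each; higher in 32 and 31 libraries than all controls of the time). A lower share of hepatocyte RNA as the only cause would raise the markers of all other cell types alike. The stellate markers rose by 0.73 ± 0.07 more than the endothelial ones. The two-sided permutation p was 1e-05, the smallest that 100000 exchanges within times can give, and 1.6e-05 adjusted over 8 tests. The endothelial reference was picked after the list results were seen, and its own score was higher by 0.08 ± 0.04 (permutation p = 0.0407, also adjusted). A lower hepatocyte share that adds to the rise is therefore not excluded. Against unequal depth, thinning all libraries to 0.839 M UMIs left the stellate median at 0.90 (0.77 at full depth). The lymphocyte median was 1.57 after thinning (2.24 at full depth), with the list still called (camera adjusted p = 1.71e-13), and the averaged calls numbered 704 (1461 at full depth). Against pancreas RNA, the lymphocyte median was 2.19 without the 8 libraries (2.24 with them). Whether the rise follows the degree of Acsf3 loss cannot be told apart from no relation: over 32 sh-Acsf3 libraries with time means removed, Acsf3 and the lymphocyte score gave r = 0.37 (permutation p = 0.124, 0.496 adjusted over 8 relations; rho = 0.27, p = 0.223, adjusted 0.892; r = 0.23 without the 2 farthest libraries). In the same libraries Acsf3 and the stellate score gave r = -0.08 (permutation p = 0.711, 0.85 adjusted over 8 relations). Acsf3 was held there by 0 to 25 UMIs per library, so counting error can hide a relation with either score. An effect of the hairpin or vector apart from Acsf3 stays open, untested, since the samples hold no other treatment. A preparation batch also stays open, since the order of the library numbers follows the treatment.

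The summed Mup CPM was lower in sh-Acsf3 by a log2 difference of -0.89 ± 0.11 (SE, n = 32 each; two-sided permutation p = 1e-05, the smallest possible; 25 of 32 libraries below all controls of the time), which argues against reads moving between near-identical Mup genes as the cause. Whether a weaker growth hormone-dependent male pattern is the cause was not decided, since genes of such a pattern need not change by equal amounts. The 15 male-biased genes outside the family had a median of -0.16 (SD 0.28), against -1.46 for the Mup genes. Of these 15, 6 fell and 1 rose. A reaction shared with the lymphocyte rise cannot be told apart from no relation, with r = -0.0729 over 32 sh-Acsf3 libraries (permutation p = 0.696, 0.85 adjusted over 8 relations; rho = -0.01, p = 0.976, adjusted 0.976; r = 0.00113 without the 2 farthest). In the same libraries the stellate score and the Mup sum gave r = -0.60 (permutation p = 0.00329, adjusted 0.0263, and r = -0.45 without the 2 farthest). Ranks gave rho = -0.52 (permutation p = 0.00809, adjusted 0.0647). Over the sh-Ctl libraries r was 0.06 (permutation p = 0.744, adjusted 0.85). The relation in sh-Acsf3 may point to a shared reaction or to a hepatocyte share that varies between libraries. It was not planned as a test of either. Loss of Acsf3, a weaker male pattern, a part played by a lower hepatocyte share, an effect of the hairpin apart from Acsf3 and a preparation batch all stay open.

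The lower acute-phase genes of sh-Acsf3 may come from the 4 sh-Ctl libraries high in Saa1, since without them the list no longer passed (camera adjusted p = 0.0532) and pointed upwards. Swapped labels are argued against, as the lowest Acsf3 level of these 4 libraries was 8.85 CPM and the highest of the sh-Acsf3 libraries of the same times was 6.40 CPM. What raised Saa1 in these 4 livers is not given by the labels, and no biological explanation was tested.

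Exchanging the treatment labels within times excluded chance for the averaged effect (1 of 100 exchanges, the real one included, gave 1461 genes or more; highest other 1). It did not for the genes with an unadjusted p under 0.05, with 306 for interaction (90 of 100; highest other 1103) and 431 for differential rhythmicity (44 of 100; highest other 1137), nor for the 12 lists called by camera (33 of 100; highest other 21). The other exchanges called a median of 9 lists at the preset correlation, so a camera call of a single list there is weak evidence by itself. With an estimated correlation 2 lists were called (1 of 100, highest other 1). Some exchanges gave several times the real count at an unadjusted p under 0.05, which may point to a structure among the samples that the groups do not hold, or to the treatment effect itself, which exchanged labels can move into these tests. Neither was tested. At single times, 1 of 35 splits, the real one included, gave as many genes at ZT0 (52, highest other 0), ZT6 (22, 6), ZT9 (36, 1), ZT12 (141, 2), ZT15 (3, 1), ZT18 (17, 4) and ZT21 (32, 3). At ZT3, 2 of 35 splits gave 7 genes or more (highest other 8). These splits cannot exclude chance for a single time. They relabelled all 8 times in 1 fit, so treatment differences of other times entered the spread and can lower the other counts. The share of 1 in 35 is also the smallest possible and was not adjusted over the 8 times. Permuted times gave fewer rhythmic genes than the real times in sh-Ctl (1954 genes, 1 of 100, highest other 20) and in sh-Acsf3 (1981, 1 of 100, highest other 36). Both treatments were permuted together in 1 fit, so real rhythms of the other treatment entered the spread and can lower the other counts. The permutations therefore exclude chance for both treatments together and not for each alone. The amplitude ratio of 0.05 was reached by 45 of 100 exchanges (highest other 0.19).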

How the results depend on the processing

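The runs without libraries high in Saa1 or with pancreas RNA were chosen only after the results were seen; the other alternatives were planned. Of the values for counts and Acsf3 over all alternatives, 358 kept their direction and side of the threshold (counts within 1.5 times), 12 lost the call, 4 gained one and 107 moved. For the 163 named genes of the averaged effect, 2221 of 2423 values were kept, 115 lost and 75 gained a call, 11 moved and 1 reversed. The causes were not tested except where stated. In the test at ZT12 alone, 44% of simulated 2-fold changes were found.

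With library size only there were 30 genes at ZT0, 14 at ZT6, 66 at ZT9 and 3 at ZT18, and Acsf3 at ZT18 lost its call (-1.73, edgeR adjusted p = 0.0676). Without a filter there were 244 at ZT0, 151 at ZT3, 198 at ZT6, 213 at ZT9, 453 at ZT12, 134 at ZT15, 107 at ZT18 and 243 at ZT21, interaction called 273, differential rhythmicity 1 (Exo1, named after it was seen), and Acsf3 at ZT21 gained a call (-1.56). There the prior degrees of freedom were infinite for all genes (median 15.4 with the filter). A mean CPM of at least 5, with fewer genes tested, gave 971 averaged and 4 at ZT18. DESeq2 gave 13 at ZT3, 7 at ZT15, 26 at ZT18 and 75 at ZT21, and called Acsf3 at ZT21 (-1.53). Limma-voom gave 26 at ZT0, 3 at ZT3, 18 at ZT9, 5 at ZT18 and 14 at ZT21. Without the shallow library there were 6 at ZT18 and 10 at ZT21. With only the 8 libraries of the time there were 41 at ZT3, 9 at ZT6, 69 at ZT12 and 10 at ZT15, and Acsf3 at ZT18 lost its call (-1.77, adjusted p = 0.068). The test with 7 degrees of freedom gave 1271 and 1319 rhythmic genes in sh-Ctl and sh-Acsf3. Camera with an estimated correlation called 2 lists, fry with a direction 17 and the mixed test of fry, for changes in either direction, 7. With fry the lists of malonyl-CoA handling, glycolysis, the TCA cycle, branched-chain amino acid breakdown, NRF2 targets and p53 targets gained a call and the acute-phase list lost its call.

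Replicate numbers were not taken to pair the libraries across groups. Of 480 pairs with the same number, 108 had a correlation of residuals over 0.1, and that share was not taken for other numbers. The mean correlation was 0.0292, and -0.00958 for other numbers. Of 64 libraries 35 correlated best with their own number, more than an even spread over 4 numbers would give. This is a hint of a replicate structure from the data, not the design. With a replicate block there were 1558 genes averaged, 12 at ZT3 and 5 at ZT15.

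Without the libraries high in Saa1 there were 13 genes at ZT3, 21 at ZT9 and 6 at ZT18, the amplitude ratio was -0.0291, and Orm2 (0.13) and the acute-phase list (camera adjusted p = 0.0532) reversed. The lists of mitochondrial fatty acid oxidation and of the TCA cycle and pyruvate dehydrogenase gained a call downwards there (camera adjusted p = 0.0366 and 0.0246). That of cholesterol synthesis and uptake gained a call upwards (camera adjusted p = 0.0246). Without those with pancreas RNA there were 23 at ZT0, 12 at ZT6, 14 at ZT9, 238 at ZT12, 1 at ZT15, 10 at ZT18 and 14 at ZT21, Acsf3 at ZT15 lost its call (-1.76, edgeR adjusted p = 0.138), the amplitude ratio was 0.117, and 1 gene list: exocrine pancreas and adipose genes, reversed (camera adjusted p = 0.747). Without each replicate number this p ranged from 0.000613 to 0.978, and the list reversed without replicate 2. Other lists that lost their call without a replicate number were those of bile acids, the acute phase and pericentral genes. Those that gained one were cholesterol synthesis, fatty acid oxidation, fatty acid synthesis, PPARalpha targets, glycolysis, branched-chain amino acid breakdown, NRF2 targets, p53 targets and the ER unfolded protein response.

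Leaving out 1 replicate number or 1 library gave 784 to 1553 genes averaged, 6 to 53 at ZT0, 3 to 10 at ZT3, 4 to 41 at ZT6, 9 to 32 at ZT9, 39 to 256 at ZT12, 1 to 5 at ZT15, 1 to 16 at ZT18 and 4 to 54 at ZT21. Interaction, rhythms, differential rhythmicity and the amplitude ratio were run without each replicate number only, not without each library. Interaction and differential rhythmicity then gave 0, rhythmic genes numbered 1167 to 1442 in sh-Ctl and 1163 to 1700 in sh-Acsf3, and the amplitude ratio was -0.00866 to 0.14. Lists called without each replicate number were 12 to 16. With 1 library left out in turn, the acute-phase list passed in 61 of 64 runs and the exocrine pancreas list in 62, and lists that did not pass in the main run passed in 11 (cholesterol synthesis), 6 (ER unfolded protein response), 4 (NRF2 targets) and 1 (branched-chain amino acid breakdown). Acsf3 without each replicate number ranged from -2.31 to -2.11 averaged, -3.54 to -2.83 at ZT0, -2.62 to -2.15 at ZT3, -3.85 to -2.91 at ZT6, -2.80 to -2.32 at ZT9, -1.81 to -1.38 at ZT12, -2.08 to -1.74 at ZT15, -2.22 to -1.55 at ZT18 and -2.22 to -1.19 at ZT21. Without 1 library of ZT21 it reached -2.469 and -1.115 there. Single libraries that moved a count by over 1.5 times, in the order of replicates, were sh-Ctl 1, 2 and 3 (19, 13, 22) and sh-Acsf3 1 and 2 (24, 9) at ZT0, and sh-Ctl 1 (3) at ZT3. At ZT6 they were sh-Ctl 1, 2 and 4 (41, 10, 11) and sh-Acsf3 1 and 3 (7, 14), and at ZT9 sh-Ctl 1 and 2 (15, 20) and sh-Acsf3 1 and 3 (18, 15). At ZT12 they were sh-Acsf3 1 and 2 (47, 256), and at ZT15 sh-Ctl 4 (1) and sh-Acsf3 1 and 4 (1, 5). At ZT18 they were sh-Ctl 1 to 4 (6, 1, 3, 3) and sh-Acsf3 1, 3 and 4 (1, 7, 6), and at ZT21 sh-Ctl 1 to 4 (9, 16, 11, 21) and sh-Acsf3 2, 3 and 4 (10, 17, 54).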

Other observations

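The genes of this part were picked after their values were seen and are reported as values of the averaged effect (edgeR, log2 difference ± SE, n = 32 per treatment). Mmp12, a macrophage elastase gene, differed by 4.81 ± 0.33 from 0.168 ± 0.251 to 4.47 ± 2.79 CPM (SD within times), the chemokine gene Ccl4 by 3.57 ± 0.28, and the interferon gamma-induced chemokine gene Cxcl9 by 1.13 ± 0.16. The lectin genes Lgals3 and Clec7a differed by 1.49 ± 0.16 and 1.35 ± 0.14, and the adhesion molecule gene Vcam1 by 1.46 ± 0.11. Pdgfrb, a receptor gene of pericytes and stellate cells, differed by 0.78 ± 0.12. All 7 of these passed and were higher at all 8 times.

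The fatty acid transporter gene Cd36 was higher by 0.85 ± 0.10, from 10.7 ± 2.63 to 19.6 ± 5.98 CPM, and the lipoprotein lipase gene Lpl by 0.81 ± 0.11. Oxct1, of ketone body use, was higher by 0.63 ± 0.10, and Hamp, which encodes the iron hormone hepcidin, by 0.57 ± 0.10, from 1550 ± 483 to 2275 ± 457 CPM. Lower were Dct at -1.14 ± 0.12, Sgpp1 at -0.49 ± 0.05, Sephs2, of selenium metabolism, at -0.40 ± 0.05, and Glo1, of methylglyoxal detoxification, at -0.38 ± 0.05. All 8 passed and kept their sign at all 8 times.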
